A study of Mus musculus with 6 samples.

How the data were processed

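The samples were 38B9 cells, a mouse B-lineage tumour line, harvested 48 h after infection with a vector carrying the LAPTM5 3'UTR or with the empty vector. Per the labels, total RNA was labelled with Cy3 and hybridized to 1-colour Agilent mouse arrays, with 3 arrays per group and 3 independent infections. Per the file headers, the slides were read with Feature Extraction 10.7.3.1 under protocol GE1_107_Sep09 and array design 014868, and the probe coordinates refer to the mm9 genome build.

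The deposited scanner files hold fluorescence intensity for each spot, with no normalization between arrays. Per the file headers, the processed intensity is background-subtracted and detrended, and a surrogate value stands in for signals near background. The raw mean intensity of each spot and the median intensity of its local background are given beside it. The deposited value table of the series holds log2 values for 79 probes; the submitters' notes name limma with no version, and the authors' normalization is not stated.

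Each array gave 43379 non-control spots for 41174 probes. Control spots and spots marked as outliers were left out and the spots of a probe were averaged. Probes were named by their accession in the reference table where it was there (27668 probes); 13506 kept the name in the files, of which 471 were updated through an older symbol. The log2 processed signal minus the 75th percentile of its array was the level used throughout. A probe was tested if it was well above background on all 3 arrays of at least 1 group, and a gene with several such probes was represented by the probe with the highest mean over the 6 arrays. This left 15420 genes, of which 12497 had a gene symbol. Levels of different probes do not compare amounts of RNA. Across probes they were used only to choose the probe of a gene and to describe signal.

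The 3 arrays with the LAPTM5 3'UTR were compared with the 3 empty vector arrays by limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors are those of the fit, and the number of arrays limits their precision: the median standard error was 0.17 on the log2 scale. Where a gene was not well above background on any array of a group, a bound is given in place of a fold: the mean of the higher group against the mean of the other, with each array of the other group set no lower than its lowest level called well above background. Such a bound is written as at least N-fold. It takes the mean of the higher group as exact and leaves out the spread of its arrays.

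A total of 29 gene lists was fixed for B-lineage identity and activation, stress, growth, metabolism, the lysosome, small-RNA pathways and markers of other cell types. The 28 lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, with adjustment over the lists. Camera with an estimated correlation and fry, which tests whether the genes of a list move one way on balance, were run beside it. Counts of members are given after adjustment over all genes and adjusted over the list alone. Genes named in the text were Laptm5 and its family, and up to 14 genes per direction with the largest difference among those past the threshold that had a gene symbol, were well above background on all arrays of the higher group and showed no overlap between groups. To these were added up to 4 members of each list past the threshold and at most 2 members of each other list, those past the threshold first and then those with the smallest p.

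The comparison, the lists, the rule for named genes and the first set of alternatives were fixed before the data were examined. The alternatives were normexp background values, quantile normalization, median centring, no filter or a stricter filter on dim probes, and the slide as a fixed or random block. Further ones were the first slide alone, the replicate number as a block, every probe or the mean of probes, eBayes with trend and robust, array weights, leaving out each array, and the deposited value table. Array position as a block, a repaired normexp, limma on the deposited value table and, for the lists, array weights, the random slide block, the mean of probes and trend and robust were added after seeing the data. With the slide as a block the difference of a gene equals that within the first slide by construction, and the fits differ in their spread and in the genes tested. Slide and position came from the deposited files: the first slide held the 3 empty vector arrays and 3'UTR replicate 1, and the second slide held 3'UTR replicates 2 and 3.

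The fit was tested on simulated data with 15420 genes in 10 runs. Of 1000 genes changed by a log2 difference of 1, 560 were recovered, and of 1000 changed by 2, 880 were recovered, with 0 of the wrong sign. Of 1532 calls, 92 (6.01%) were false. The simulated arrays held no effect of slide or array position, whereas another split of the real arrays called 82 genes. The 6.01% therefore does not carry over to the genes called on the real arrays. A list shifted by 0.5 was called in 10 of 10 runs, with 1 other list called in 270 tests. The simulated genes were independent, whereas the estimated correlation in the ribosomal protein list was 0.765. The false calls of lists in the simulation therefore do not carry over to the real arrays. When the real arrays were split 3 and 3 in other ways, 3 to 9 lists were called. The simulated shift was also larger than the 0.29 median of the glycolysis list.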

Results

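Gene expression was measured in 6 cultures of 38B9 mouse B-lymphoma cells, 3 infected with the LAPTM5 3'UTR and 3 with the empty vector, 48 h after infection. LAPTM5 is a transmembrane protein of lysosomes in blood cells, and the comparison asks which genes differ when its 3' untranslated region is overexpressed. Between 56.2% and 60.4% of the spots of each array were well above background, and 0 spots were saturated. The median local background was 33 to 36 intensity units on every array. The first slide held the 3 empty vector arrays and 3'UTR replicate 1, and the second slide held 3'UTR replicates 2 and 3.

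Laptm5 itself gave a strong signal in both groups and did not pass the test between them. Its probe on chromosome 4 from 130490785 to 130490844 (mm9), at base 1123 of the transcript, gave 6067, 6799 and 6851 processed intensity units with the empty vector and 6640, 7371 and 6328 with the 3'UTR. The log2 difference was 0.042 with a 95% interval from -0.33 to 0.41 (limma on all probes, n = 3 per group, adjusted p = 0.936). The other probe, from 130490893 to 130490952 at base 1231, gave a log2 difference of 0.17 with an interval from -0.29 to 0.63 (adjusted p = 0.765). The deposited labels state neither the species nor the ends of the expressed segment, so these probes cannot show whether it was expressed. Of the rest of the family, Laptm4a had a log2 difference of 0.014 (adjusted p = 0.978), and Laptm4b was not tested because no array showed it well above background.

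More genes were lower than higher in cells with the 3'UTR. Adamts7, a secreted metalloprotease, and Marcks, an actin-binding substrate of protein kinase C, fell by 3.99 ± 0.28 and by 2.94 ± 0.14 on the log2 scale (SE, n = 3 per group). Pdcd1, which encodes the inhibitory receptor PD-1, and Tiam2 rose by 1.84 ± 0.15 and 2.47 ± 0.12. Of 15420 genes tested, 161 passed the threshold in limma, 56 higher and 105 lower, and 1977 had an unadjusted p under 0.05. The fitted difference was at least 2-fold for 44 higher and 80 lower genes, and over 4-fold for 5 and 24. These counts do not use the bounds. Of the 56 higher genes, 8 were not well above background on any empty vector array, and of the 105 lower genes, 15 on any 3'UTR array. For such genes, Fgf21 among them, the size of the fold was not established. The groups did not overlap for any of the 161 genes; over all tested genes they did not overlap for 2791 (18.1%), where chance gives 10%. With the slide as a block, 45 genes passed, of which 31 were among the 161, and within the first slide, where 3'UTR replicate 1 stood alone and was assumed to vary like the empty vector arrays, 169 passed, of which 56 were among them. The block fit rests on the same array, and its differences equal those within the first slide by construction. All 161 genes kept their direction in the block fit, which was fixed in advance because the groups did not overlap for any of them. Their median was 1.03 times the difference without the block, while the median standard error of the 130 genes without a call in the block fit went from 0.15 to 0.23. The balance turned within the first slide, with 99 higher and 70 lower, and with array weights, with 609 higher and 506 lower. The count of 161 became 34, 55 and 29 without empty vector replicates 1, 2 and 3, 59 and 48 without 3'UTR replicates 1 and 3, and 155 without 3'UTR replicate 2, and it was 0 with normexp background values, where 216 genes had an unadjusted p under 0.05.

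**Figure D1:**
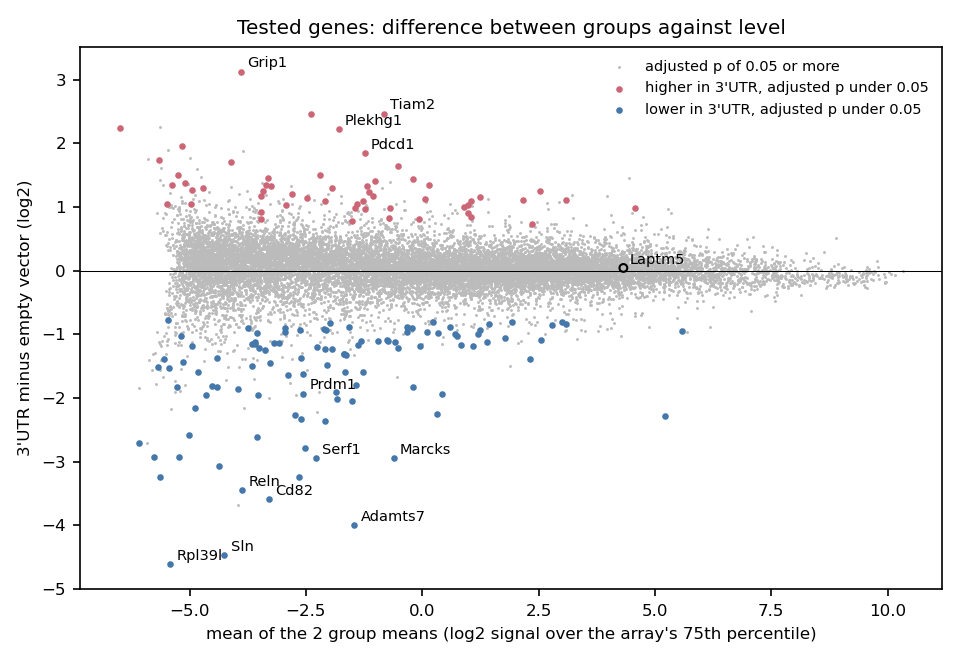
Each point is 1 of the 15420 tested genes, with its mean log2 level over both groups (relative to the array's 75th percentile) on the horizontal axis and the log2 difference, 3'UTR minus empty vector, on the vertical axis. The 56 higher and 105 lower genes past the threshold are coloured, and Laptm5, with a log2 difference of 0.042, lies among the other genes.

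Among the higher genes, Grip1, a scaffold protein with PDZ domains, rose by 3.12 ± 0.18 on the log2 scale (adjusted p = 0.000807), with 1 of 3 empty vector arrays well above background, although it was 0.72 and did not pass with repaired normexp background values (adjusted p = 0.0583). Plekhg1 rose 4.69-fold (adjusted p = 0.00106). Pdcd1 rose 3.58-fold (adjusted p = 0.00335), and the RNA-binding protein gene Pcbp4 rose 3.14-fold (adjusted p = 0.00357). The adhesion molecule gene Nectin4 and the cell-surface glycoprotein gene Mpzl1 were 3.27-fold and 2.71-fold higher. Galnt3, which starts O-linked glycosylation, was 2.65-fold higher on its main probe (adjusted p = 0.00986), while a second probe gave a log2 difference of 0.54 (adjusted p = 0.761). The mitochondrial topoisomerase gene Top1mt and the selenium-binding protein gene Selenbp1 were both 2.54-fold higher. A further 4 genes were not well above background on any empty vector array. These were the actin-binding protein gene Nexn (at least 2.62-fold higher, adjusted p = 0.0217), the glutathione transferase gene Gsta4 (at least 2.24-fold, adjusted p = 0.0113), the export pump gene Abcc2 (at least 1.71-fold, adjusted p = 0.0237) and the metabolic hormone gene Fgf21 (at least 1.14-fold, adjusted p = 0.0215). Of the 14 higher genes, 6 passed with the slide as a block (Grip1, Tiam2, Plekhg1, Pdcd1, Pcbp4 and Galnt3) and 9 within the first slide, and 5 of those 6, all but Galnt3, passed without each array in turn. The 8 genes without a call in the block fit had 0.942 to 1.16 times their difference there. Of the 14, 9 lost their call without at least 1 array, with adjusted p up to 0.155, and with normexp background values Fgf21, Nexn, Abcc2, Nectin4, Gsta4 and Selenbp1 turned lower. With the repaired form those 6 and Grip1 did not pass. Abcc2, Fgf21 and Gsta4 were at 0.0052, 0.015 and 0.036, and Nexn, Nectin4 and Selenbp1 at 0.19, 0.26 and 0.32. The normexp offset pulls dim probes towards 0, so these lost calls do not tell whether the differences depend on the background correction. The other 7 passed at 0.567 to 0.847 times their difference.

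Among the lower genes, Rpl39l, a paralogue of a ribosomal protein, was at least 6.28-fold lower (adjusted p = 0.000199), and Sln, which encodes the calcium-pump regulator sarcolipin, was at least 12.9-fold lower (adjusted p = 0.0113). Neither was well above background on any 3'UTR array by its main probe. The same held for the mRNA export factor gene Nxt2 (at least 3.33-fold lower), the collagenase gene Mmp13 (at least 2.73-fold) and the potassium channel subunit gene Kcne3 (at least 2.02-fold). A second probe of Rpl39l and one of Sln were not well above background on any array, so each of these falls rests on 1 probe. A second Kcne3 probe, not tested, was well above background on 2 empty vector arrays and 1 3'UTR array. Adamts7 was 15.9-fold lower and Marcks 7.68-fold lower (adjusted p = 0.0015 and 0.000562). The tetraspanin gene Cd82 fell by 3.58 ± 0.51 and the extracellular glycoprotein gene Reln fell by 3.44 ± 0.24 on the log2 scale, each with 2 of 3 3'UTR arrays well above background. Fam169b (9.43-fold), Serf1 (7.67-fold), Pgpep1l (6.87-fold) and the transporter gene Slc35f2 (6.14-fold) were well above background on all 6 arrays. Tfpi, which encodes a coagulation inhibitor, fell by 3.07 ± 0.40 on the log2 scale on its main probe (adjusted p = 0.0215), with 1 of 3 3'UTR arrays well above background. A second Tfpi probe was lower too (adjusted p = 0.0431), with 0 of 3 3'UTR arrays well above background, and the other tested probe gave -0.72 (adjusted p = 0.638). Of the 14 lower genes, 10 passed with the slide as a block, 13 within the first slide and 9 without each array in turn; Sln, Cd82, Tfpi and Mmp13 lost their calls in the block fit, at 0.958 to 1.17 times their difference. With repaired normexp background values the differences shrank, as the normexp offset makes them do for dim probes. Nxt2, Mmp13 and Kcne3 did not pass (-0.47, -0.44 and -0.36). The other 11 passed at 0.183 to 0.754 times their difference, with Rpl39l at -0.85, Sln at -1.26 and Adamts7 at -2.605. How much of the shrinkage came from the offset was not tested. Without some arrays another probe stood for 2 of the genes: for Kcne3 it gave -2.01 (adjusted p = 0.318) without empty vector replicate 2, and for Tfpi it gave -0.66, -0.74 and -0.76 without empty vector replicates 1, 2 and 3. Of all 28 named genes, 18, 19 and 16 passed without empty vector replicates 1, 2 and 3, and 19, 26 and 20 without 3'UTR replicates 1, 2 and 3.

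**Figure D2:**
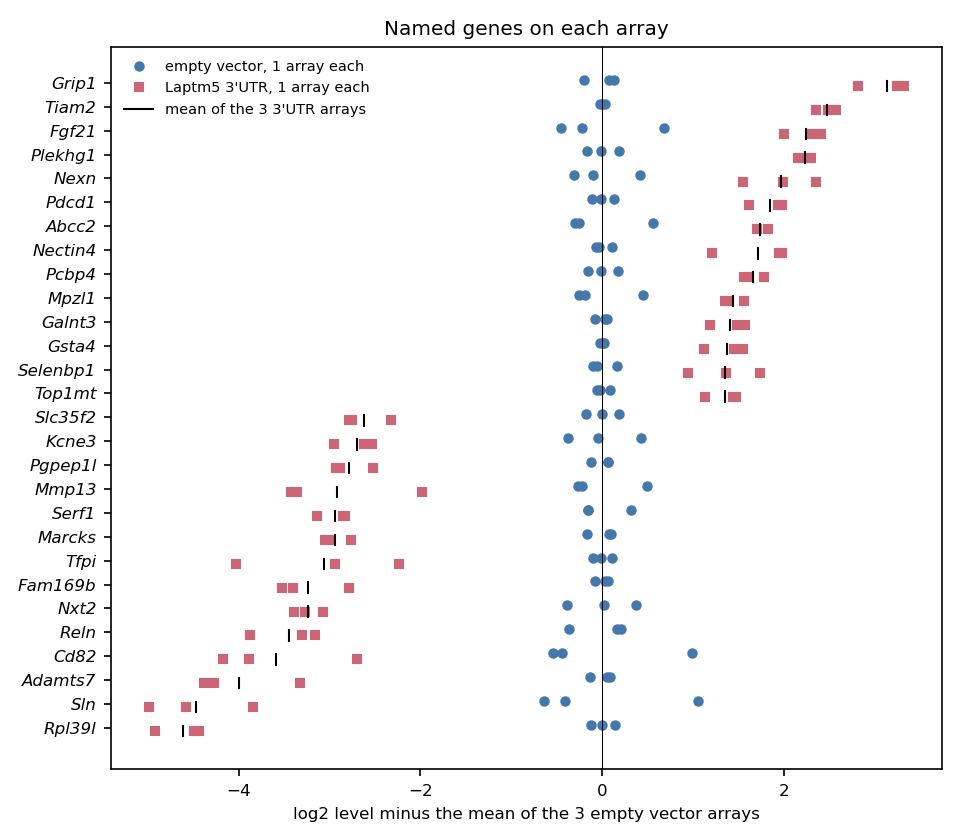
Each circle is 1 empty vector array and each square 1 3'UTR array, for the 14 higher and 14 lower named genes, as the log2 level minus the mean of the 3 empty vector arrays; black bars are the means of the 3 3'UTR arrays. Squares and circles do not overlap for any of the 28 genes, although the direction of Fgf21, Nexn, Abcc2, Nectin4, Gsta4 and Selenbp1 turned with normexp background values.

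The list of glycolysis and hypoxia genes had a positive median. Of 34 tested members, 27 had a positive difference and 1 rose past the threshold over all genes, P4ha1, which encodes a collagen prolyl hydroxylase subunit (0.84 ± 0.13 on the log2 scale, adjusted p = 0.0372). Adjusted over the list alone, 7 rose and 1 fell. The hypoxia-induced gene Ankrd37 had a log2 difference of 0.92 (adjusted p = 0.0706) and the phosphofructokinase gene Pfkl one of 0.73 (adjusted p = 0.12), while Ndrg1, also known to respond to hypoxia, had -1.38 (adjusted p = 0.0538). The median of the list was 0.29 (camera adjusted p = 8.34e-05), and the adjusted p was 0.615 with an estimated correlation. The median was 0.32 both with the slide as a block (adjusted p = 0.000288) and within the first slide (adjusted p = 0.000661). P4ha1 did not pass with the slide as a block (0.80, adjusted p = 0.322), nor without any 1 of the 6 arrays, where its adjusted p ran from 0.0628 to 0.196.

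The lists of histones, mitosis and DNA replication had negative medians. Of 29 tested histone genes, 27 had a negative difference and 2 fell past the threshold, H2bc4 by 1.21 ± 0.15 and H1f2 by 1.03 ± 0.13 on the log2 scale (adjusted p = 0.0205 and 0.02); adjusted over the list alone, 3 fell. Among the others, H2bc21 gave -0.51 (adjusted p = 0.139) and H1f1 gave -0.42 (adjusted p = 0.307). The median was -0.22 (camera adjusted p = 1.16e-05, and 0.615 with an estimated correlation), with -0.24 in the block fit (adjusted p = 0.000444) and -0.24 within the first slide (adjusted p = 0.000661). Per array, 3'UTR replicate 3 lay above 2 of the 3 empty vector arrays (0.12 against 0.083, 0.28 and -0.042). Of 41 mitosis genes, 34 had a negative difference and 0 passed, with 0 adjusted over the list alone and 3 at an unadjusted p under 0.05; examples are Cenpf at -0.86 (adjusted p = 0.389) and Dlgap5 at -0.33 (adjusted p = 0.326). Their median was -0.15 (camera adjusted p = 0.000173, and 0.615 with an estimated correlation), and it was -0.15 in both slide fits (adjusted p = 0.0687 with the block, 0.0376 within the first slide). Of 51 DNA replication genes, 38 had a negative difference and 0 passed, with 0 adjusted over the list alone and 4 at an unadjusted p under 0.05; Rrm1, a ribonucleotide reductase subunit, gave -0.39 (adjusted p = 0.277) and Ccne2 gave -0.81 (adjusted p = 0.365). Their median was -0.081 (camera adjusted p = 0.00776, and 0.615 with an estimated correlation), with -0.062 in both slide fits (adjusted p = 0.435 and 0.355). With normexp background values the medians of these 3 lists turned to 0.095, 0.14 and 0.22, although none of them was counted as reversed with the repaired form. The histone median was -0.12 without empty vector replicate 2 and -0.13 without 3'UTR replicate 2, the mitosis median was -0.26 without empty vector replicate 2, and the replication list lost its call without empty vector replicate 3 (adjusted p = 0.0924) or 3'UTR replicate 2 (adjusted p = 0.148) and had a median of -0.13 without 3'UTR replicate 3. H2bc4 and H1f2 lost their calls with the slide as a block (-1.11 and -1.07, adjusted p = 0.179 and 0.145); H2bc4 lost its call without any 1 array (adjusted p from 0.0502 to 0.0982), and H1f2 without each array except 3'UTR replicate 2 (adjusted p from 0.0592 to 0.0919).

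The lists of B-cell identity had small shifts. Of 27 early B-lineage and pre-B genes, Cnn3, which encodes an actin-binding calponin, rose by 1.10 ± 0.18 on the log2 scale (adjusted p = 0.0398), 0 fell and 26 did not pass; 1 rose adjusted over the list alone. Rag1, a recombinase of antigen receptor genes, had a log2 difference of -0.88 (adjusted p = 0.172). The list median was -0.10 (camera adjusted p = 0.0461, and 0.615 with an estimated correlation), and -0.17 in both slide fits (adjusted p = 0.112 with the block, 0.0424 within the first slide). Of 28 genes of B-cell receptor signalling, 0 passed, with 0 adjusted over the list alone and 5 at an unadjusted p under 0.05; the kinase genes Blk and Syk gave -1.40 (adjusted p = 0.0966) and -0.73 (adjusted p = 0.174). Their median was -0.058 (camera adjusted p = 0.0478, and 0.615 with an estimated correlation), and -0.078 in both slide fits (adjusted p = 0.224 and 0.166). Both lists turned higher with normexp background values, at medians of 0.11 and 0.080, but neither was counted as reversed with the repaired form. Prdm1, which drives plasma cell differentiation, fell by 1.93 ± 0.26 (adjusted p = 0.0226) and was the 1 gene of 11 in the plasma cell list that passed, over all genes and adjusted over the list alone; that list as a whole did not pass (median -0.021, camera adjusted p = 0.207). The 18 germinal centre genes did not pass as a list either (median -0.11, camera adjusted p = 0.417); 2 fell adjusted over the list alone, and Bcl6 gave -0.57 (adjusted p = 0.103). The early B list kept its call without 3'UTR replicate 2 (adjusted p = 0.0118) and lost it without any other array (adjusted p from 0.0539 to 0.111); the receptor list kept its call without 3'UTR replicate 3 (median -0.10, adjusted p = 0.0374) and lost it without any other array (adjusted p from 0.0772 to 0.133), with a median of -0.028, -0.046 and -0.060 without empty vector replicates 1, 2 and 3 and -0.020 and -0.015 without 3'UTR replicates 1 and 2. Cnn3 lost its call with the slide as a block (1.33, adjusted p = 0.117) and without each array except 3'UTR replicate 2 (adjusted p from 0.0793 to 0.174), and Prdm1 kept its call with the block and lost it without each array except 3'UTR replicate 2 (adjusted p from 0.0507 to 0.103).

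The lists of interferon response genes and of T-cell and myeloid markers had negative medians whose size rested on some of the arrays. Of 38 interferon genes, 27 had a negative difference and 0 passed over all genes, with 5 at an unadjusted p under 0.05; adjusted over the list alone, 1 rose and 1 fell. Gbp3 had a log2 difference of -0.99 (adjusted p = 0.103) and Bst2 one of 1.08 (adjusted p = 0.0828). The median was -0.21 (camera adjusted p = 0.00378, and 0.615 with an estimated correlation), and -0.19 in both slide fits (adjusted p = 0.074 with the block, 0.0376 within the first slide). Of 15 tested T-cell and NK markers, 12 had a negative difference and 0 passed, with 4 at an unadjusted p under 0.05 and 2 lower adjusted over the list alone; Zap70 gave -0.83 (adjusted p = 0.137). Their median was -0.19 (camera adjusted p = 0.00541, and 0.615 with an estimated correlation), with -0.35 in the block fit (adjusted p = 0.00908) and -0.28 within the first slide (adjusted p = 0.067). Of 17 tested myeloid and mast-cell markers, Csf2ra, a cytokine receptor chain, fell by 1.10 ± 0.11 (adjusted p = 0.00986), which was also the 1 gene lower adjusted over the list alone, and the lysozyme gene Lyz2 gave -0.59 (adjusted p = 0.217). Their median was -0.16 (camera adjusted p = 0.0304, and 0.632 with an estimated correlation), with -0.41 in both slide fits (adjusted p = 0.000288 and 0.000661). The groups overlapped for the T-cell list, where 3'UTR replicate 3 was at 0.13 and empty vector replicate 3 at -0.098, and for the myeloid list, where 3'UTR replicate 2 was at 0.086 and empty vector replicates 1 and 3 at 0.076 and -0.025. The interferon median was -0.090 without empty vector replicate 2, -0.12 without 3'UTR replicate 3 and within 1.5 times of the full value without any other array. The T-cell list lost its call without empty vector replicate 2 (median -0.029, adjusted p = 0.135), 3'UTR replicate 1 (-0.19, adjusted p = 0.135) or 3'UTR replicate 2 (-0.098, adjusted p = 0.148), and its median was -0.31 without empty vector replicate 3 and -0.30 without 3'UTR replicate 3. The myeloid list lost its call without empty vector replicate 2 (median -0.094, adjusted p = 0.308) or 3'UTR replicate 1 (-0.014, adjusted p = 0.43), and its median was -0.29 without empty vector replicate 3. Csf2ra did not pass with the slide as a block (-1.10, adjusted p = 0.106) or without empty vector replicate 1 (adjusted p = 0.0654) or 3 (adjusted p = 0.0787).

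The list of cholesterol synthesis genes had a negative median, and the ribosomal protein and oxidative phosphorylation lists had small shifts that rested on single arrays. Of 25 cholesterol genes, 19 had a negative difference and 0 passed, with 0 adjusted over the list alone and 5 at an unadjusted p under 0.05. The synthase gene Hmgcs1 gave -0.43 (adjusted p = 0.294). Their median was -0.21 (camera adjusted p = 0.000732, and 0.615 with an estimated correlation), with -0.13 in both slide fits (adjusted p = 0.112 and 0.067) and -0.12 without 3'UTR replicate 2. Of 76 ribosomal protein genes, 71 had a negative difference and 0 passed, with 0 adjusted over the list alone and 0 at an unadjusted p under 0.05 in limma; Rps3a1 gave -0.26 (adjusted p = 0.516). Their median was -0.10 (camera adjusted p = 0.00165, and 0.779 with an estimated correlation), with -0.045 in both slide fits (adjusted p = 0.331 and 0.2). Of 67 oxidative phosphorylation genes, 47 had a negative difference and 0 passed, with 0 adjusted over the list alone and 1 at an unadjusted p under 0.05; Uqcrh gave -0.48 (adjusted p = 0.134). Their median was -0.071 (camera adjusted p = 0.0116, and 0.779 with an estimated correlation), and it turned to 0.0095 in both slide fits (adjusted p = 0.868 and 0.994). With normexp background values the medians of the last 2 lists turned to 0.26 and 0.29, while neither was counted as reversed with the repaired form. Without empty vector replicate 2 or 3'UTR replicate 2 the ribosomal median was 0.018 or 0.00672 and the oxidative phosphorylation median 0.017 or 0.023, with neither list past the threshold. Without empty vector replicates 1 or 3 or 3'UTR replicate 3 the ribosomal median was -0.18, -0.16 or -0.20, and without 3'UTR replicate 3 the oxidative phosphorylation median was -0.13.

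**Figure D3:**
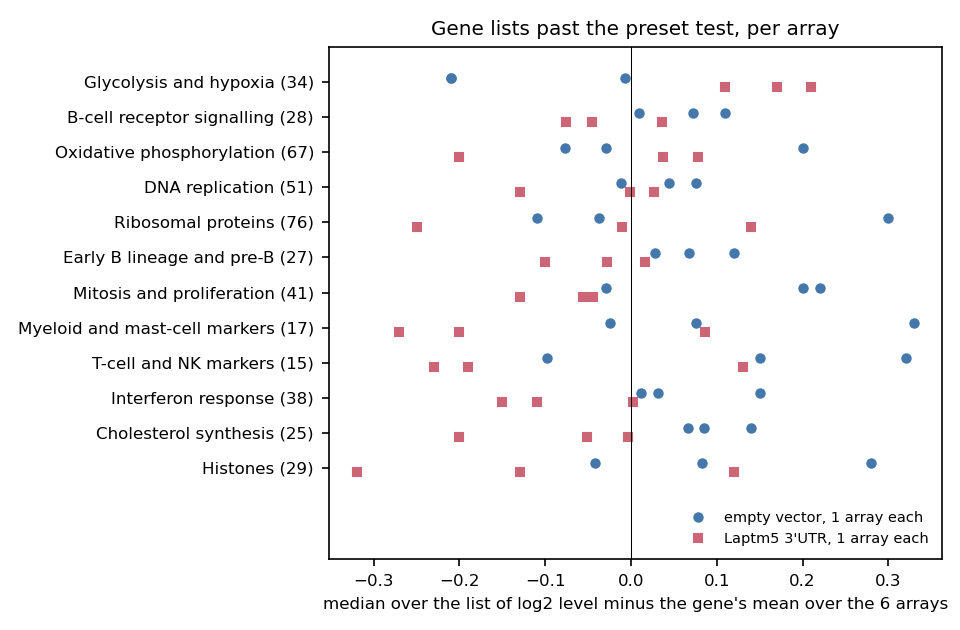
Each mark is the median over the tested members of a list (their number in brackets) of the log2 level minus the gene's mean over the 6 arrays, for 1 empty vector array (circles) or 1 3'UTR array (squares), for the 12 lists past the preset test. Squares and circles lie apart for 5 lists (glycolysis, early B lineage, interferon, mitosis and cholesterol) and overlap for the other 7. With normexp background values 7 of the lists turned higher, and none of those was counted as reversed with the repaired form.

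The other lists did not pass. In the p53 target list of 32 genes, Cd82 fell past the threshold, Zmat3 had a log2 difference of 0.85 (adjusted p = 0.0538), and the list had a median of 0.14 (camera adjusted p = 0.521); adjusted over the list alone, 1 rose and 3 fell. Adjusted over the list alone, 2 of 25 immediate early genes rose and 1 fell (Egr2 at 0.65, Jun at -0.69), with a median of 0.23 (camera adjusted p = 0.201), and 1 of 22 antigen presentation genes fell (H2-Ob at -1.27), with a median of -0.046 (camera adjusted p = 0.417). The stress lists had medians of 0.094 for the unfolded protein and integrated stress response (camera adjusted p = 0.149; Slc7a3 at 0.66) and -0.00058 for heat shock (camera adjusted p = 0.658; Hspb1 at 0.47). The median was 0.061 for lysosome genes (camera adjusted p = 0.584; Gla at 0.46), -0.0074 for autophagy genes (camera adjusted p = 0.309; Map1lc3a at -0.61) and 0.11 for LAPTM5 partners and HECT ligases (camera adjusted p = 0.417; Cbl at 0.31). It was 0.13 for NF-kB targets (camera adjusted p = 0.417; Bcl2a1b at -1.95), -0.073 for apoptosis regulators (camera adjusted p = 0.201; Bbc3 at 0.83) and 0.11 for MYC targets (camera adjusted p = 0.309; Myc at 0.48). The small-RNA list had a median of -0.022, a mean of 0.014 and a camera direction that was down while fry pointed up (camera adjusted p = 0.991; Igf2bp2 at 0.55). Erythroid and megakaryocyte markers had a median of 0.17 (camera adjusted p = 0.367) and fibroblast and epithelial markers one of 0.21 (camera adjusted p = 0.317; Krt8 at 0.53). The last list had a median of -0.11 in both slide fits. Of the 12 lists that passed, 4 also passed with the slide as a block, a fit that rests on 3'UTR replicate 1. The unfolded protein and integrated stress response list and the MYC list passed there as well (camera adjusted p = 0.0282 and 0.0218). With an estimated correlation 0 lists passed, and 0 with fry, whose smallest adjusted p was 0.326. Its test for change in either direction was passed by 7 of the 28 tested lists, 5 of them among the 12.

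Arrays of the same group were not always more alike than arrays of different groups. Pearson's r across tested genes, which are not independent replicates, was 0.9911 to 0.9958 within groups and 0.9847 to 0.9934 between groups. It was 0.9929 to 0.9958 among the empty vector arrays, which shared a slide, and 0.9911 to 0.9917 among the 3'UTR arrays. Empty vector replicate 3 with 3'UTR replicate 1, on the same slide, gave 0.9934. Empty vector replicate 1 with 3'UTR replicate 2, on different slides, gave 0.9926. The first principal component carried 41.4% of the variance and the second 25.6%. On the first, the empty vector arrays lay at -32.1 to -11.2 and the 3'UTR arrays at 2.89 (replicate 1), 18.0 and 41.5. Slide and group are therefore mixed on it.

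The deposited value table held 79 probes for 70 gene names, and all 79 were higher with the 3'UTR, by a log2 difference of at least 0.98. Its values differed from quantile-normalized log2 processed signals by at most 0.021. Of these 79 probes, 52 passed the threshold when every probe was tested. The table held 0 lower probes, whereas 135 probes were lower past the threshold here, 102 of them at least 2-fold; whether it is the full table of the authors is not stated.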

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

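Array position as a block, the repaired background correction, limma on the deposited table and, for the lists, array weights, the random slide block, the mean of probes and eBayes with trend and robust were chosen after seeing the data; the other alternatives were planned. The 161 calls kept their direction under every alternative that tested them except normexp (142) and its repaired form (159). With the slide as a fixed block, within the first slide and without single arrays this was fixed in advance for genes that kept their probe. The reason is that the groups did not overlap for any of the 161. The stricter filter tested 127 of the 161. The number of calls moved widely, and signal over background limited 9 of the 28 named genes to bounds. Planned normexp gave 0 higher and 0 lower genes (216 at an unadjusted p under 0.05). On empty vector replicate 1, 12 spots had a local background over 10 times the median, and the background mean of the fit was -478 there against -7.55 to -5.83 on the other arrays. With those spots repaired, 43 were higher and 93 lower, 89 of them shared. No filter gave 10 and 27 of 27334 tested genes. The slide as a fixed block gave 9 and 36, as a random block 91 and 160, and the first slide alone 99 and 70 (1 array against 3). Array weights gave 609 and 506. Array position as a block gave 256 and 276 with positions 3 and 4 taken as one, and 0 and 1 with them apart, where 1 residual degree of freedom was left and 2939 genes had an unadjusted p under 0.05. Leaving out 1 array gave 8 to 60 higher and 21 to 95 lower genes: 11 and 23, 23 and 32, and 8 and 21 without empty vector replicates 1, 2 and 3, and 21 and 38, 60 and 95, and 16 and 32 without 3'UTR replicates 1, 2 and 3. Apart from the replicate block below, the other alternatives gave 44 to 76 higher and 80 to 146 lower genes. A cause was tested only for normexp, by the repair.

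The replicate number as a block gave 22 higher and 61 lower genes, 66 of them shared with the 161. The deviations of arrays with the same number from their group means correlated at -0.385, -0.272 and -0.382, so no pairing by number was seen. Deviations cancel within a group, so positive values for other pairs push these down. A weaker pairing by number therefore stays open. The block leaves the differences as they were, with 2 residual degrees of freedom against 4, so the lower count does not measure a weaker effect. Empty vector replicates 1, 2 and 3 correlated instead with 3'UTR replicates 2, 3 and 1, at 0.48, 0.399 and 0.56. That pairing was seen in the data and matches the position block with 256 and 276 genes; the 161 calls do not use it.

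Of the lists, 6 passed with the slide as a fixed block, 0 with an estimated correlation, 0 with fry, 7 without empty vector replicate 2 and 7 to 11 without 1 array; the other fits gave 8 to 13. Limma on the deposited table called all 79 probes against 52, but that table holds only probes that were at least 0.98 higher, so this count shows little. Under planned normexp the following reversed: Fgf21 -0.50, Nexn -0.305, Abcc2 -0.50, Nectin4 -0.23, Gsta4 -0.47, Selenbp1 -0.14, and the lists of B-cell receptor signalling 0.080, DNA replication 0.22, early B lineage 0.11, histones 0.095, mitosis 0.14, oxidative phosphorylation 0.29 and ribosomal proteins 0.26. Oxidative phosphorylation also turned to 0.0095 with the slide as a block, and the cause was not tested. With the repaired normexp 9 lists passed, and none of the genes and lists named here was counted as reversed.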

Other observations

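The groups of genes in the next paragraph were chosen after their values were seen. So were the tests of the patterns that follow, except the slide as a block and 3 others: the held-out arrays, the identity of paired probes and the olfactory receptor probes well above background on at least 1 array.

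Most genes of a cluster on chromosome 6 were lower with the 3'UTR. The Gimap genes, which encode GTPases of lymphocytes, lie side by side there from 48627839 to 48715093 (mm9). Of 9 tested probes for 7 Gimap genes, 8 had a negative difference and 6 passed the threshold, all lower: Gimap3 by both probes (-1.59 and -1.56), Gimap4 (-0.93), Gimap6 (-0.96), Gimap9 (-0.93) and 1 of the 2 Gimap5 probes (-1.87; the other gave -0.35, adjusted p = 0.35). Gimap1 gave -0.22 and Gimap7 gave 0.19, and neither passed. The median of the 9 probes was -0.93, and it lay between -0.997 and -0.73 under every scaling and background alternative, both slide fits and without each array; 1 probe passed in either slide fit, and 2, 3 and 1 passed without empty vector replicates 1, 2 and 3 and 2, 4 and 1 without 3'UTR replicates 1, 2 and 3. At the immunoglobulin heavy chain locus on chromosome 12, 31 of 36 tested probes had a negative difference and 6 passed, all lower, with a median of -0.68. That median was -0.59 in both slide fits, where 0 probes passed in limma and 14 (block) or 17 (first slide) had an unadjusted p under 0.05; 2, 1 and 1 passed without empty vector replicates 1, 2 and 3, and 0, 3 and 0 without 3'UTR replicates 1, 2 and 3. Of 14 probes taken for the kappa light chain locus, 7 had a negative difference and 0 passed in limma, with 2 at an unadjusted p under 0.05. Their median was 0.0034 and lay between -0.165 and 0.164 without single arrays. It turned to -0.052 with quantile normalization, -0.53 with normexp background values and -0.23 in both slide fits. These probes do not cover the whole span from 68071741 to 70557901 on chromosome 6. A gene without a symbol inside it, from 68199611 to 68199670, was left out of the set and passed, at -0.89 (limma adjusted p = 0.0263). Probes for variable segments can bind more than 1 segment, so their number does not count separate genes. Csf2rb and Csf2ra, chains of cytokine receptors, fell by 1.83 and 1.10, although a second Csf2rb probe lay 2.13 log2 units away. Socs1, an inhibitor of cytokine signalling, fell by 1.39, and Prkcq, a protein kinase C of lymphocytes, fell by 1.48. Among the higher genes, S1pr1, the sphingosine phosphate receptor that guides lymphocytes, rose by 1.34, and Selenbp2 rose by 1.25 beside its paralogue Selenbp1. Whether the probes of these paralogues bind each other's RNA was not tested, so they may not be separate changes.

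The first pattern is the 161 genes past the threshold, since both slide and group separate 3'UTR replicates 2 and 3 from the empty vector arrays. A difference between the slides is argued against for the 31 genes that passed with the slide as a block, a comparison within the first slide that rests on 3'UTR replicate 1 alone, so an effect of that array stays open for them. For the other 130 it cannot be told apart from the 3'UTR, since only 1 3'UTR array shared a slide with the controls. A held-out test took the 161 genes with the smallest p on 4 arrays, a new set each time rather than the 130. Between 3'UTR replicate 1 and held-out empty vector replicate 2, 3 or 1 they kept a median share of 0.608, 0.769 or -0.347. The 2 arrays held out for the last value lie on opposite sides in the second pattern below. Whether that pattern gave the negative share was not tested. Of the 10 splits of the 6 arrays into 3 and 3, the real one gave the most genes, 161 against 82 in the highest other. It also gave the most lists, 12 against 9. At an unadjusted p under 0.05 in limma it did not rank first. Empty vector replicates 1 and 3 with 3'UTR replicate 2, set against the rest, gave 3018 genes against 1977 for the real split. That other split had 0 genes past the threshold. In any case 10 splits are too few for a share under 0.05. In the block fit these 130 had a median of 1.03 times their difference (quartiles 0.958 and 1.09), all in the same direction, while the median standard error went from 0.15 to 0.23, but they were chosen with that array among the 6, so an effect of the 3'UTR and one of the slide both stay open for them.

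The second pattern is a structure of the arrays that the groups do not explain: empty vector replicate 1 and 3'UTR replicates 2 and 3 differed from the other 3 arrays in 82 genes, all higher on the first 3, with 0 shared with the 161. Examples are Hoxb9, Gp1bb and Ephb4. The median level of the 82 was -4.27 against 0.051 for all tested genes, which describes signal over different probes and not amounts of RNA. Subtracting local medians over the array surface, or medians per bin of GC content and level, ended the calls. Their adjusted p in limma had lain between 0.035 and 0.049. The median difference went from 1.44 only to 1.31 (quartiles 1.07 and 1.61) or 1.13 (0.886 and 1.43), so neither subtraction removed the differences. However, the 82 genes were picked by their difference in these data, in the other split with the most genes. That choice alone can keep a difference large, so whether either cause or chance led to the calls stays open. Olfactory receptor probes, from genes that B cells are not known to express, were higher on the same 3 arrays for 617 of 957 (median 0.126, quartiles -0.042 and 0.467), and for 359 of the 421 well above background on at least 1 array (median 0.373), a choice that depends on the signal itself. Over all 957, empty vector replicate 1 (-0.023) lay below empty vector replicate 2 (0.091), so whether a product on those 3 arrays gives signal for unexpressed genes stays open, and no biological explanation was tested.

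The third pattern is that lower genes lay near each other: 9 pairs of neighbours within 500 kb, among them Slc35f2 with Sln, Pgpep1l with Fam169b, H2bc4 with H1f2 and 3 pairs of Gimap genes, against a mean of 4.61 in 10000 random draws (permutation p = 0.04). The 3 Gimap pairs come from the chromosome 6 cluster described above, and the count of pairs was not tested without them. The higher genes had 1 pair against 1.48 (permutation p = 0.78). Loss of a segment spanning the neighbours is argued against for 5 pairs, since the 24 tested genes between the outermost lower genes, called or not, had a median of -0.029 (quartiles -0.24 and 0.18), and stays open for the 4 pairs with no tested gene between them: Slc35f2 with Sln, Pgpep1l with Fam169b, Gimap9 with Gimap4 and Gimap4 with Gimap6. Cross-hybridization is argued against, since 0 pairs had probes sharing at least 75% of bases (40.7% to 51.2%). The slide stays open for those without a call in the block fit, the permutation p lies close to the threshold, and no biological explanation was tested.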
